A study of Homo sapiens with 6 samples.

How the data were processed

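RNA was measured in 6 samples of the human Toledo lymphoma line, 3 treated with the CARM1 inhibitor TP-064 at 5 uM and 3 with DMSO, for 6 days. Per the labels' protocols, RNA was extracted with a column kit and made into stranded libraries of polyadenylated RNA. Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.0 and DESeq 1.18.0 were used with the hg38 build. The gene annotation release, the strand setting of the counting and any filter on rows are not given in the sources used here. Groups and replicate numbers come from the sample labels, and each column of the deposited table was matched to a sample by its name.

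The authors deposited 1 table of 18278 genes with a signal per gene and sample, the gene count divided by a size factor for the sample. In each column every value was a whole multiple of 1 step within a tolerance of 0.001, so that 100% of values came out as whole reads. The inverse of the step equalled the median-of-ratios size factor recomputed from those reads, at 1.14, 1.01 and 0.985 for TP-064 replicates 1, 2 and 3 and 0.963, 1.01 and 0.925 for DMSO replicates 1, 2 and 3. In TP-064 replicate 2 and DMSO replicate 2 the size factor lies close to 1, and a step that near to 1 cannot be told from rounding by its size alone. For these 2 columns the recovery rests on the unrounded decimals of the values and on the recomputed size factor, so depths, scalings and count tests that use their reads carry that limit. Each listed gene had at least 10 recovered reads in at least 1 library. The recovered totals were 41354131 to 48360867 reads per library, and they bound the counting error only. In tests on data simulated from these libraries, 16058 genes were tested. Changes were planted in 100 genes at each fold, all with a mean of at least 200 normalized read counts. The procedure recovered 98% of genes changed 1.5-fold and 100% of genes changed 2-fold, with 3.41% of its calls false. Genes of lower mean, and a response as broad as the measured one, are not covered by these shares.

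The design fixed before the data were examined named edgeR on raw counts as the test, and limma for the case of normalized values. The table held normalized values, so limma 3.58.1 in R 4.3.3 was used, with the trend option, on log2 of the normalized read count plus a pseudocount of 1. Genes with a mean of at least 10 over the 6 samples were tested, which left 2230 out. The fit had 4 residual degrees of freedom and no replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and a second count required a change of at least 2-fold. Fold changes are TP-064 minus DMSO on that log2 scale, which understates changes of low genes. Means and SDs are of normalized read counts.

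Lists of genes, 27 in number, were fixed before the data were examined, and 26 of them had at least 5 tested members. Several share genes. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and members were also adjusted over the list alone. Named genes followed a rule fixed at the same time. It takes CARM1, CREBBP and EP300, then the 8 largest rises and 8 largest falls among called genes with a mean of at least 200 normalized read counts and groups that do not overlap, and passes over pseudogenes, unnamed loci, immunoglobulin segments and genes of the sex chromosomes that mark sex. From each list it takes up to 2 called members with the smallest p in the main direction and 1 in the other. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

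Symbols and coordinates come from GENCODE release 29 on GRCh38, matched by gene identifier without its version for 18214 of 18278 genes. The chi-square of reads between replicates lay above sampling noise for each pair, from 3.21 to 8.10 per degree of freedom, so no library was counted as a repeat of another. Opposite-strand reads were measured over antisense genes with at least 50% of their exon length covered by exons of listed genes on the other strand. The partner was the overlapping gene with the highest mean, which had to be at least 1000, and its own overlap could be smaller. The 95% intervals come from 2000 bootstrap draws over genes.

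Alternatives planned beforehand were median-of-ratios factors in edgeR 4.0.16, library size scaling, no filter, a filter at 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block, each replicate left out, a threshold of 0.01, a null of a 1.2-fold change, camera with an estimated correlation, fry, and pseudocounts of 0.5 and 5. The design also named its count test, edgeR with TMM, as an alternative on recovered reads. Added after the data were seen were TMM scaling in limma and leaving out genes that overlap an exon on the opposite strand. Leaving out TP-064 replicate 3 was planned and was given a second look for its opposite-strand reads. Tests on counts used the recovered reads of all 6 columns and serve only as alternatives, where edgeR with TMM called 10657 genes and DESeq2 9485. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.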

Results

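Toledo is an established human line derived from a diffuse large B cell lymphoma and grown in suspension. It was used here in a study of CARM1 inhibition in lymphomas with mutations in the acetyltransferase genes CREBBP and EP300. CARM1 is an arginine methyltransferase that modifies histones and transcriptional coactivators, and TP-064 is a small molecule that inhibits its activity. Messenger RNA was sequenced from 3 samples treated for 6 days with 5 uM TP-064 and from 3 samples treated with the solvent DMSO over the same time. The reads assigned to the 18278 listed genes came to 48360867, 44309088 and 41354131 in TP-064 replicates 1, 2 and 3, and to 44426731, 47051434 and 43044383 in DMSO replicates 1, 2 and 3. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

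The comparison of TP-064 with DMSO asks which transcripts differ after prolonged inhibition of CARM1. Genes of the cell division cycle were lower after TP-064. All 45 tested genes of DNA replication and S phase fell, with a median log2 fold change of -1.57, and all 39 tested genes of mitosis fell, with a median of -1.82. The largest rise among well expressed named genes was in YPEL4, at 1176 ± 22.9 normalized read counts after TP-064 and 5.12 ± 2.58 after DMSO (SD, n = 3 each). BMP7, a secreted ligand of the TGF-beta family, had the largest fall among such genes, to 162 ± 33.4 from 1832 ± 15.1 normalized read counts (SD, n = 3 each). Most MHC class II presentation genes moved the other way from the cell cycle genes, with 12 of 17 tested members higher, 1 lower and 4 not called. That list passed camera at the preset correlation (adjusted p = 0.00273), and no list passed with an estimated correlation.

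CARM1 mRNA itself was lower in each TP-064 sample than in any DMSO sample. Its normalized read counts were 3401, 3500 and 3371 after TP-064 and 4003, 3884 and 4217 after DMSO, a log2 fold change of -0.24 (SE 0.04, limma adjusted p = 8.1e-05). With scaling to library size alone CARM1 was at -0.11 and still passed the test. The gene lies on chromosome 19 from 10871513 to 10923070 on the plus strand of GRCh38. The compound acts on the protein, so this level does not test the labels. EP300, on chromosome 22 from 41091786 to 41180079, rose by a log2 fold change of 0.24 (SE 0.05, limma adjusted p = 0.00118), or 0.36 with library size scaling and 0.17 at the lowest with 1 replicate left out, with 4151, 3597 and 3573 normalized read counts after TP-064 against 3298, 3227 and 3070. CREBBP, on chromosome 16 from 3725054 to 3880726, did not pass the test, with a log2 fold change of 0.06 (SE 0.05, limma adjusted p = 0.368). Its TP-064 samples read 4253, 3539 and 3959 and its DMSO samples 3834, 3618 and 3806 normalized read counts. CREBBP crossed the threshold without TP-064 replicate 2, at 0.13, and with scaling to library size alone, at 0.18, and its leave-one-out values ran from -0.00314 to 0.129.

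Of 16048 genes tested, 10449 (65.1%) passed a limma adjusted p of 0.05, 5112 of them higher and 5337 lower after TP-064. Among protein-coding genes, 8952 of 12166 passed. A change of at least 2-fold was found for 2097 genes, 1045 higher and 1052 lower. The values of the 3 treated samples did not overlap those of the 3 controls for 11086 of the 16048 tested genes, where chance gives 10%. Against a null of a 1.2-fold change in place of no change, 5592 genes passed, 2687 higher and 2905 lower. Called genes split almost evenly by direction, with 48.9% higher, but scaling to library size alone moved the median of all genes to 0.13 from 0.01 and gave 61.6% higher among 10809 calls.

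The first principal component held 75.0% of the variance and separated the groups. The second held 11.6% and spread the TP-064 libraries, with replicate 3 at -35.2 and replicates 1 and 2 at 21.3 and 16.8. The DMSO libraries lay between them, from -6.37 to 1.89. Correlations of log values between TP-064 replicates were 0.995 for replicates 1 and 2, and 0.989 and 0.990 for the pairs that include replicate 3. The DMSO pairs each reached 0.995, and pairs across the groups lay between 0.966 and 0.973. Reads of antisense genes were more frequent in TP-064 replicate 3. For 269 antisense genes with at least 50% of their exon length covered by opposite-strand exons, reads were compared with the most abundant overlapping gene. The median share of that partner's reads was 0.704% in replicate 3 (95% bootstrap interval 0.602 to 0.846) and between 0.0758% and 0.115% in the other 5 libraries. Without this replicate 10131 genes were called, 9817 of them among the calls from all 6 samples.

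**Figure D1:**
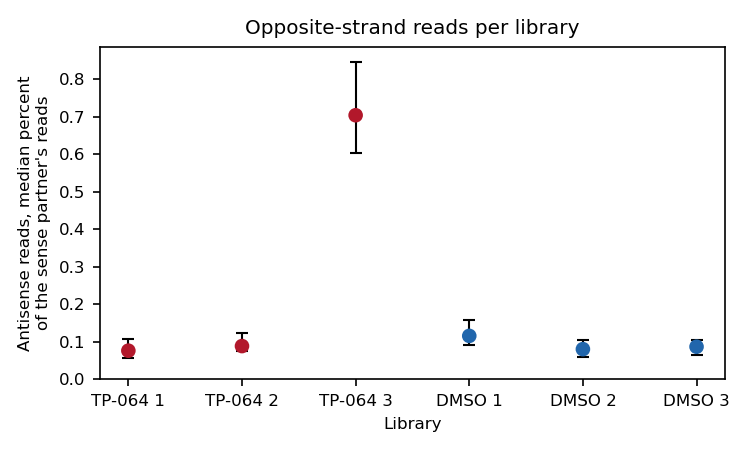
Reads of 269 antisense genes as a percent of the reads of their partner on the other strand, median per library (y axis, percent) with 95% bootstrap intervals over genes, for the 3 TP-064 libraries (red) and the 3 DMSO libraries (blue). TP-064 replicate 3 stands at 0.704% and the other 5 libraries between 0.0758% and 0.115%.

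Of the 8 largest rises among well expressed genes, YPEL4, on chromosome 11 from 57645087 to 57649944, had a log2 fold change of 7.70 (SE 0.26), and SERPINB2, a serine protease inhibitor of the plasminogen activator system on chromosome 18 from 63871692 to 63903890, 6.51 (SE 0.22). ITGA6, the integrin alpha 6 subunit, rose by 5.16 (SE 0.18). DNTT, the template-independent polymerase that adds bases at V(D)J junctions in lymphocyte precursors, rose by 4.42 (SE 0.06), to 5063 ± 213 from 235 ± 15.9 normalized read counts (SD, n = 3 each). TNFRSF13C, the receptor for the B cell survival factor BAFF, rose by 3.75 (SE 0.05), to 5694 ± 223 from 423 ± 30.7. RNF152, a ubiquitin ligase of the lysosome, rose by 4.21, TRIM72 by 3.94 and SYTL2, a synaptotagmin-like protein of vesicle transport, by 3.41. The limma adjusted p of these genes lay between 4.01e-16 for DNTT and SYTL2 and 3.00e-12 for ITGA6. DMSO levels of YPEL4, SERPINB2 and ITGA6 were near the lower end of the measurement, at 5.12, 3.83 and 13.9 normalized read counts, and a pseudocount of 1 understates folds of such genes.

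The 8 largest falls began with BMP7, on chromosome 20 from 57168748 to 57266629, at -3.51 (SE 0.10), and IL21R, the receptor of interleukin 21, on chromosome 16 from 27402162 to 27452042, at -3.30 (SE 0.08). CDC42BPB, a kinase bound by CDC42, changed by -2.94, the ETS factor ETV4 by -2.83, and the chloride and proton exchanger CLCN4 by -2.82. TUBB2B, a beta tubulin, changed by -2.74, HSPA6, an inducible HSP70 chaperone, by -2.70, and the replication-dependent histone gene HIST1H3F by -2.67. The limma adjusted p of these genes lay between 1.00e-14 for CLCN4 and 1.36e-10 for ETV4. TUBB2B, HSPA6 and HIST1H3F have near-identical relatives that can share reads, so their values are uncertain. YPEL4, ITGA6, CDC42BPB, ETV4, TUBB2B and CARM1 overlap an exon of a listed gene on the opposite strand, and the strand setting of the counting is not given in the sources used here.

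**Figure D2:**
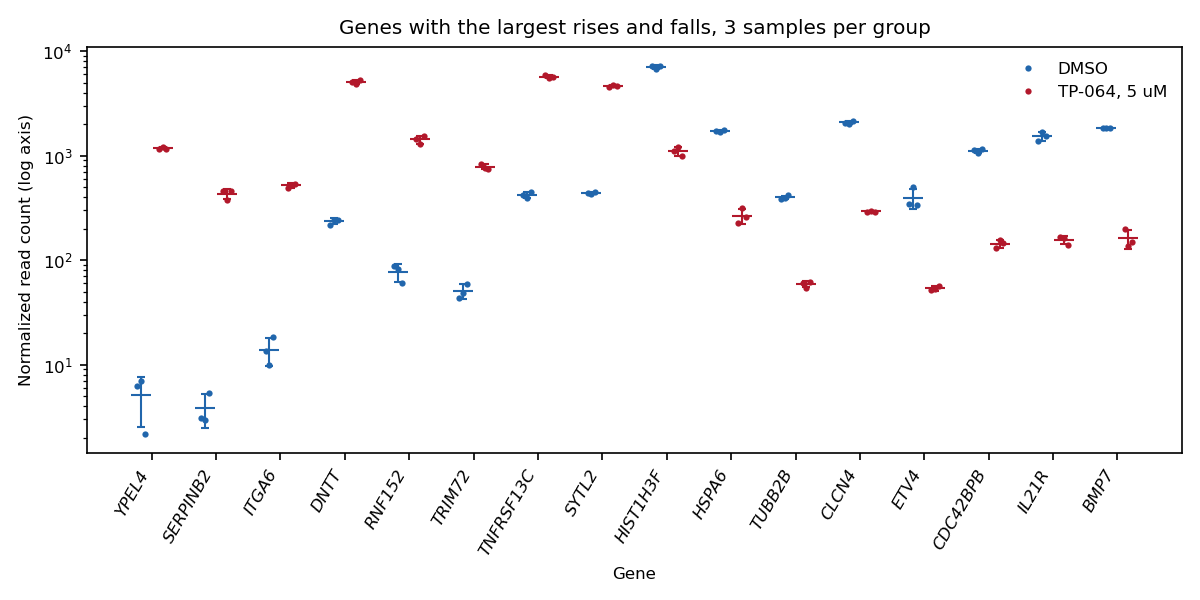
Normalized read counts (y axis, log scale) of the 8 genes with the largest rises and the 8 with the largest falls (x axis), with 1 point per sample, a horizontal line at the group mean and bars of 1 SD, for 3 TP-064 samples (red) and 3 DMSO samples (blue). The groups do not overlap for any of these genes, from YPEL4 at 5.12 in DMSO and 1176 in TP-064 to BMP7 at 1832 and 162.

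Among the 26 gene lists with at least 5 tested members, 9 passed camera with a preset correlation of 0.01, a test that compares a list with all other genes. None passed when the correlation between members was estimated for each list. With 4 residual degrees of freedom that setting gave no adjusted p under 0.598, even for the replication and mitosis lists, where every tested member fell. A list that misses it is therefore not shown to be unchanged. The count of called members therefore stands beside each list, first over all genes and then adjusted over the list alone. The median and the mean log2 fold change had opposite signs in the lists of acetyltransferases, deacetylases, B cell receptor signalling, pro-apoptotic genes, anti-apoptotic genes, myeloid markers and epithelial, stromal and erythroid markers, none of which passed camera. Among named members, KIF2C, DDIT4, ACAT2, ALDOC, PSME2, PSMB9, BLNK, MEF2C, TNFAIP3, POLH, CFLAR, PRMT5, HDAC2 and VIM overlap a listed exon on the opposite strand.

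The replication list had a median of -1.57, with 45 of 45 members lower, and 45 adjusted over the list alone. The camera adjusted p was 6.19e-26, and the adjusted p = 0.598 with an estimated correlation, within a range of 1.58e-32 to 0.598 over the alternatives tested with camera, as are the ranges of the other lists. E2F2, a transcription factor of S phase entry, changed by -2.27 (SE 0.04), to 3649 ± 143 from 17629 ± 555 normalized read counts (SD, n = 3 each). CDC6, which loads the replicative helicase, changed by -2.23 (SE 0.05). The mitosis list had 39 of 39 members lower, and 39 adjusted over the list alone, with a camera adjusted p of 3.56e-25. Its adjusted p = 0.598 with an estimated correlation, within a range of 2.38e-31 to 0.598. BUB1B, a kinase of the spindle checkpoint, changed by -2.11 (SE 0.04) and KIF2C, a kinesin of the centromere, by -2.04 (SE 0.04).

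Genes of ribosome biogenesis and of the MYC response were lower by a smaller amount, with a median of -0.43. In that list 28 of 33 members fell and 0 rose, with 29 lower and 1 higher adjusted over the list alone. The camera adjusted p was 3.73e-09, and the adjusted p = 0.598 with an estimated correlation, within a range of 2.02e-10 to 0.598. NCL, the nucleolar protein nucleolin, and LDHA, lactate dehydrogenase A, each changed by -1.08. MYC, singled out after its value was seen, had a log2 fold change of 0.09 (SE 0.04, limma adjusted p = 0.0519 over all genes). It was the 1 member that passed as higher when adjusted over the list alone. Genes of cytosolic ribosomal proteins moved both ways, with 21 higher and 14 lower of 75 (21 and 13 adjusted over the list alone), and their list did not pass camera (adjusted p = 0.625). With scaling to library size alone that list passed as higher (adjusted p = 0.00824), and its adjusted p ranged from 0.00824 to 0.931 over the alternatives. RPL13A rose by 0.35, RPL31 rose by 0.28 and RPS16 fell by 0.43, and processed copies of such genes make their counts uncertain.

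Metabolic and stress lists were also lower. Of 28 genes of the ATF4 amino acid response, 21 fell and 2 rose (22 and 2 adjusted over the list alone), with a median of -0.39 and a camera adjusted p of 4.48e-05. The adjusted p = 0.841 with an estimated correlation, within a range of 7.81e-06 to 0.841. PHGDH, the first enzyme of serine synthesis, changed by -1.50 (SE 0.05) and SLC7A1, a transporter of cationic amino acids, by -0.97 (SE 0.04), while DDIT4, an inhibitor of mTORC1, rose by 1.34 (SE 0.05). Of 27 genes of sterol synthesis and uptake, 20 fell and 6 rose (20 and 7 adjusted over the list alone), with a median of -0.48. Their camera adjusted p was 0.00263, and the adjusted p = 0.841 with an estimated correlation, within a range of 0.000940 to 0.841. ACAT2, which makes acetoacetyl-CoA for the pathway, changed by -1.26 (SE 0.04). Genes that rose in that list included ABCA1 (1.07) and, chosen after their values were seen, ABCG1 (1.15) and MYLIP (0.42). ABCA1 and ABCG1 export cholesterol and MYLIP marks the LDL receptor for degradation.

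Of 23 genes of the unfolded protein response, 15 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -0.31 and a camera adjusted p of 0.00473. The adjusted p = 0.841 with an estimated correlation, within a range of 0.00186 to 0.841. XBP1, a transcription factor of that response and of plasma cells, changed by -1.06 (SE 0.04) and MANF by -0.93 (SE 0.04), while ERN1, the sensor that splices XBP1 mRNA, rose by 1.34 (SE 0.06). Of 29 genes of hypoxia and glycolysis, 16 fell and 5 rose, with the same counts adjusted over the list alone and a median of -0.43. The camera adjusted p was 0.0190, and the adjusted p = 0.914 with an estimated correlation, within a range of 0.00798 to 0.914. PKM, pyruvate kinase, changed by -0.88 (SE 0.04) and ALDOC, an aldolase, rose by 1.28 (SE 0.05). Without genes that overlap an exon on the opposite strand, 5 lists passed, and the sterol, unfolded protein and hypoxia lists no longer did (camera adjusted p of 0.660, 0.141 and 0.145). Their medians were then -0.16 for the sterol list, -0.31 for the unfolded protein list and -0.41 for the hypoxia list. With scaling to library size alone the median of the unfolded protein list was -0.19.

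In MHC class II presentation 12 of 17 members rose and 1 fell, with the same counts adjusted over the list alone, a median of 0.25 and a camera adjusted p of 0.00273. The adjusted p = 0.841 with an estimated correlation, within a range of 0.00116 to 0.841. HLA-DOA, a modulator of peptide loading, rose by 0.69 (SE 0.04) and CTSS, the protease that trims the invariant chain, by 0.43 (SE 0.04), while RFXAP, a subunit of the factor that binds class II promoters, fell by 0.40 (SE 0.11). In MHC class I presentation 11 of 19 members fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.15. The camera adjusted p was 0.0289, and the adjusted p = 0.914 with an estimated correlation, within a range of 0.00774 to 0.914. PSME2, an activator of the proteasome, changed by -1.12 (SE 0.04) and the immunoproteasome subunit PSMB9 by -0.96 (SE 0.05). The class I list lost its call without TP-064 replicate 3 (camera adjusted p = 0.0776, median -0.14) and with a filter at 1 CPM (0.0588, median -0.15). It also lost it with library size scaling (0.127), at a median of -0.03, and without overlapping genes (0.681), at -0.08. Of 5 groups of protein-coding genes by mean, the highest had a median log2 fold change of -0.14, close to that of the class I list. No list was compared with genes of matched mean. Reads of HLA genes can be shared between related copies, so their values are uncertain.

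**Figure D3:**
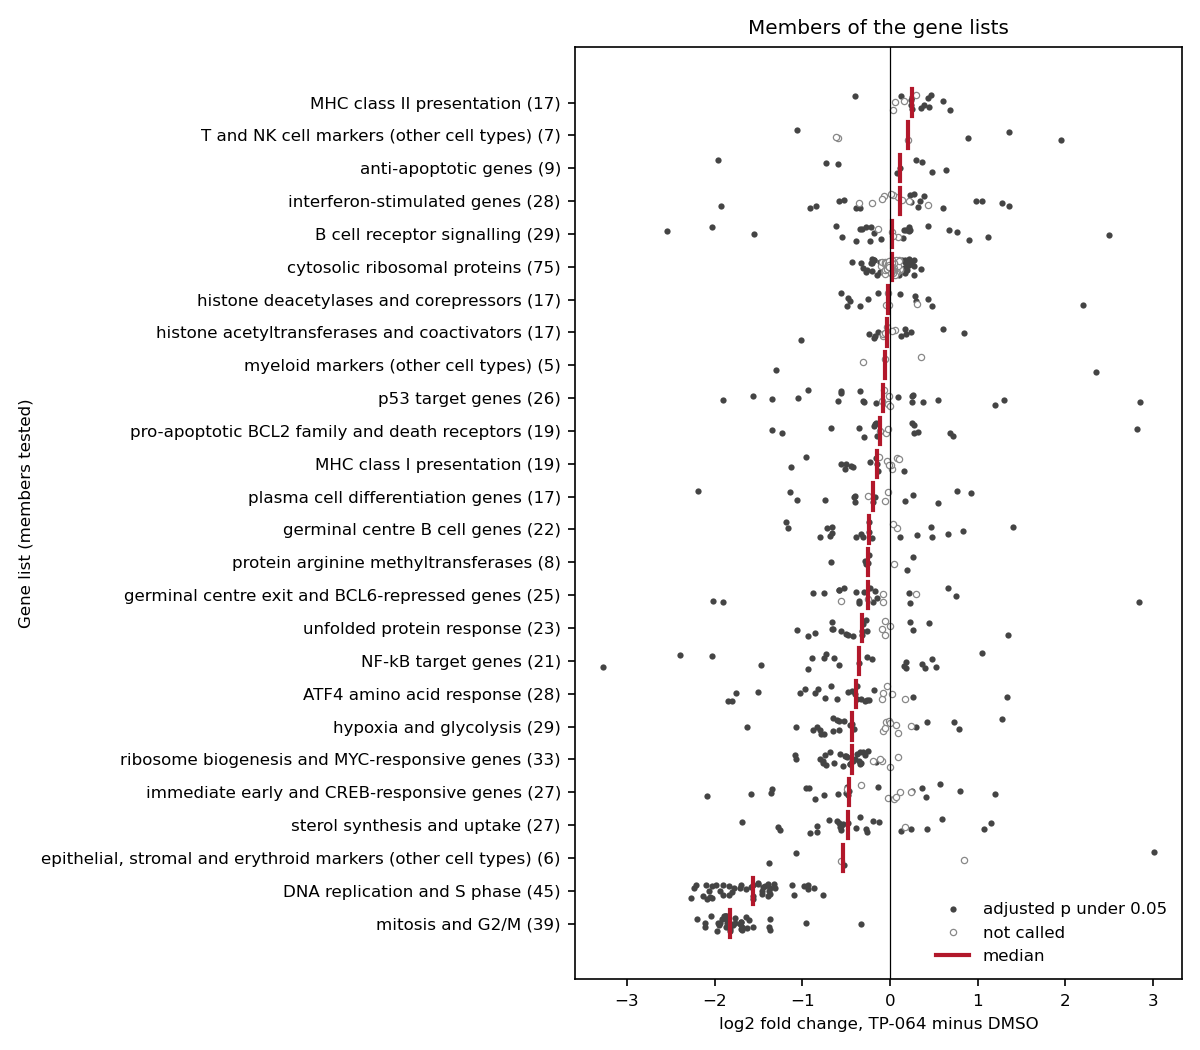
log2 fold change of each tested member (x axis, TP-064 minus DMSO, on log2 of the normalized read count plus 1) in each of the 26 gene lists (y axis, number of tested members in parentheses), with filled points for a limma adjusted p under 0.05, open points for the rest and a red line at the list's median. The replication and mitosis lists lie apart from the others, with medians of -1.57 and -1.82.

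B cell lists held large changes in both directions and did not pass camera. Of 29 genes of B cell receptor signalling, 12 rose and 13 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.828). BLNK, an adaptor below the receptor, rose by 2.50 (SE 0.04), to 11970 ± 119 from 2110 ± 97.8 normalized read counts (SD, n = 3 each). CD22, an inhibitory coreceptor, changed by -2.54 (SE 0.07). Of 22 germinal centre genes, 7 rose and 13 fell (8 and 13 adjusted over the list alone, camera adjusted p = 0.761). MEF2C rose by 1.40 (SE 0.05), while EZH2, the methyltransferase of H3 lysine 27, changed by -1.16 (SE 0.03) and MYBL1 by -1.19 (SE 0.07). Of 25 genes of germinal centre exit and BCL6 repression, 5 rose and 15 fell, with the same counts adjusted over the list alone. That list missed the threshold (camera adjusted p = 0.0576) and crossed it without TP-064 replicate 2 (0.0461) and with no filter on low values (0.0349), within a range of 0.0349 to 0.914. GPR183, a receptor for oxysterols, rose by 2.84 (SE 0.10), and CHEK1, a checkpoint kinase, changed by -2.01 (SE 0.05). Of 17 plasma cell genes, 5 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.591). TNFRSF17, the receptor BCMA, rose by 0.93 (SE 0.05) and PRDX4 changed by -0.75 (SE 0.04).

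Signalling and survival genes were divided too. All 21 tested NF-kB target genes changed, 8 higher and 13 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.389). TNFAIP3, a feedback inhibitor of the pathway, rose by 1.06 (SE 0.03), while lymphotoxin beta (LTB) changed by -2.04 (SE 0.11) and CD83 by -0.76 (SE 0.05). Of 27 immediate early genes, 6 rose and 14 fell (6 and 15 adjusted over the list alone, camera adjusted p = 0.451). KLF2 changed by -1.34 (SE 0.10) and ATF3 by -1.36 (SE 0.10), and BTG2, an antiproliferative gene, rose by 1.2 (SE 0.04). Of 28 interferon-stimulated genes, 11 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.625). STAT2 rose by 1.36 (SE 0.03) and IRF7 by 0.61 (SE 0.05), and HERC5 changed by -1.93 (SE 0.09).

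Of 26 p53 target genes, 9 rose and 12 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.625). TP53INP1 rose by 2.85 (SE 0.05), while CDKN1A, the cell cycle inhibitor p21, changed by -1.90 (SE 0.09), DDB2 by -1.56 (SE 0.06) and POLH by -1.05 (SE 0.03). Of 19 pro-apoptotic genes, 7 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.861). BIK, a BH3-only protein, rose by 2.81 (SE 0.08), and PMAIP1, which encodes NOXA, changed by -1.23 (SE 0.06). Each of the 9 tested anti-apoptotic genes changed, 6 higher and 3 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.770). MCL1 rose by 0.36 (SE 0.03) and CFLAR by 0.48 (SE 0.05), and BIRC5, or survivin, also a mitosis gene, changed by -1.96 (SE 0.05).

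Chromatin enzymes related to the target showed mostly small changes. Of 8 arginine methyltransferases, 2 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.451). PRMT1 changed by -0.67 (SE 0.04), PRMT5 by -0.28 (SE 0.03) and PRMT9 by 0.26 (SE 0.05), with PRMT5 at -0.15 when scaled to library size alone. Of 17 acetyltransferases and coactivators, 6 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.861). CRTC1, a coactivator of CREB, rose by 0.84 (SE 0.08), NCOA1 rose by 0.60 (SE 0.05) and HAT1, which acetylates new histone H4, changed by -1.01 (SE 0.04). Of 17 deacetylases and corepressors, 6 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.861). HDAC11 rose by 2.20 (SE 0.15), while HDAC2 changed by -0.56 (SE 0.04) and RCOR1 by -0.49 (SE 0.04).

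Few markers of other cell types were expressed. Of 7 tested T and NK cell markers, 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.761). PRF1 rose by 0.89 (SE 0.09) and TRAC by 1.36 (SE 0.20), while TRBC2 changed by -1.06 (SE 0.06). Of 5 myeloid markers, 1 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.861). CSF1R rose by 2.35 (SE 0.32), to 64.3 ± 13.3 from 12.6 ± 6.20 normalized read counts (SD, n = 3 each). CD14 changed by -1.30 (SE 0.41, limma adjusted p = 0.0117), from 16.8 ± 5.29 to 6.26 ± 2.40, and lost its call without DMSO replicate 1 (-1.2, adjusted p = 0.0524) and with DESeq2 (-1.42, adjusted p = 0.0543), within an adjusted p range of 0.00639 to 0.0543 over the alternatives. Of 6 epithelial, stromal and erythroid markers, 1 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.733). PECAM1 rose by 3.02 (SE 0.14), and VIM changed by -0.52 (SE 0.04) and COL1A1 by -1.07 (SE 0.09). None of the 13 mitochondrially encoded transcripts in the list fixed for RNA quality was found in the deposited table, so that check could not be made.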

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

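Leaving out genes that overlap an opposite-strand exon and TMM scaling in limma were chosen after the result was seen, while the design had named edgeR with TMM. In the 20 alternatives that called genes no call turned direction. Of 91 named genes, 88 kept their direction and side of the threshold in each of the 18 gene fits that tested them, and 9 of 26 lists in each alternative that tested them. The count of 10449 called genes lay between 8969 and 10809 except where fewer genes were tested or the null was a 1.2-fold change, which gave 5592 (2687 higher, 2905 lower) by construction. Without overlapping genes 7255 of 11139 were called. The 9 called lists became 0 with an estimated correlation, 16 with fry, which tests a list on its own and not against other genes, and 5 without overlapping genes, where fewer genes were tested. CREBBP passed with library size scaling (0.18, adjusted p = 0.0160) and, among leave-one-out fits, ran from -0.00314 to 0.129, past the threshold only without TP-064 replicate 2 (adjusted p = 0.0145), within an adjusted p range of 0.0145 to 0.963. The cause was not tested. Leaving out each replicate called between 9732 and 10247 genes. No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.0859, 0.0659 and -0.0793, and not every sample correlated best with its own number. Deviations from means of 3 samples hold much noise, so they cannot rule a pairing out. The replicate block called 10491 genes, 10328 of them among the calls without it. DESeq2 gave no list test. Depth limits the low genes: 2230 genes were below the mean of 10 and were not tested.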

Other observations

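The tests on the source of the antisense reads in TP-064 replicate 3, expression level, scaling, GC content and length, cell cycle phase, antisense genes without a shared exon, and other splits of the samples were chosen only after the result was seen, as were the genes and groups named here, but not those on all antisense genes and on lincRNAs without replicate 3.

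Replication-dependent histone genes were lower after TP-064 along with the replication list. Of 58 tested genes of the histone clusters, 55 fell and 2 rose, with a median log2 fold change of -1.83 and values from -4.14 to 1.21. HIST1H4C, a histone H4 gene, stood at 12401 ± 997 normalized read counts after TP-064 and 48071 ± 466 after DMSO (SD, n = 3 each), a log2 fold change of -1.96 (SE 0.05). HIST1H1C, a linker histone gene, changed by -1.59 (SE 0.06). Copies in these clusters are near-identical, so single members are uncertain. The libraries select polyadenylated RNA, so the level of the group as a whole is uncertain as well. Small nucleolar RNA genes had 51 of 103 lower and 4 higher, with a median of -0.48. The selection of polyadenylated RNA makes their levels uncertain too, and they were not compared with the genes they lie in.

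HBEGF, a ligand of the EGF receptor, rose by 3.20 (SE 0.05), to 30829 ± 954 from 3367 ± 231 normalized read counts (SD, n = 3 each). TEC, a kinase related to BTK, rose by 2.93 (SE 0.04), and IL7R, the interleukin 7 receptor of lymphocyte precursors, by 2.57 (SE 0.09). The chemokine gene CCL4 changed by -3.27 (SE 0.29) and TNF by -2.39 (SE 0.18), both from low DMSO levels of 66.8 and 113 normalized read counts. FCGR2B, the inhibitory Fc receptor of B cells, changed by -2.03 (SE 0.14).

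TP-064 replicate 3 held more reads of antisense genes, with 212 genes at 10 or more reads there and at most 3 in each other library, 161 of them antisense. The next 2 comparisons took only genes with a mean of at least 5 and under 200 normalized read counts over all libraries. Replicate 3 enters that mean, so genes can be included through its own reads, which can enlarge a difference. In that library antisense genes that share exon sequence with a gene on the other strand exceeded antisense genes that share none by 0.324 log2. This excess is relative to replicates 1 and 2 (95% interval 0.264 to 0.402) and fits a partial loss of strand information in that library. Genomic DNA or unspliced RNA would also raise intronic genes and lincRNAs that share no such exon, and their median excess was -0.0154 (-0.0481 to 0.0151). The inhibitor would raise the share in replicates 1 and 2, whose higher value, 0.0881%, lay below the highest DMSO value of 0.115%. A loss of strand information may therefore be the cause, found and tested on the same data.

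The medians of antisense genes and lincRNAs were higher after TP-064, at 0.26 and 0.20 on the log2 scale against -0.02 for protein-coding genes. Of 1055 tested antisense genes 286 were called higher and 104 lower, and of 831 lincRNAs 243 and 104. Of 12166 protein-coding genes 4170 were called higher and 4782 lower. Replicate 3 as the whole cause is argued against, in these libraries alone, for lincRNAs that share no opposite-strand exon, at 0.199 without it (0.145 to 0.251). The same holds for antisense genes that share none, at 0.176 (0.123 to 0.274). Both intervals are over genes and hold no spread between samples. For all antisense genes that cause cannot be told apart. Their median without replicate 3 was 0.142, with an interval of 0.0996 to 0.182 that reaches the bound of 0.1 set beforehand. Protein-coding genes of low expression were also higher, and a trend with expression level cannot be told apart either: the excess over protein-coding genes of matched mean was 0.0932 (0.0568 to 0.121), above 0 but on both sides of 0.1. An effect of the inhibitor on these transcripts stays open.

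The 84 tested genes of the replication and mitosis lists had a joint median of -1.74 (-1.83 to -1.64, an interval over genes that vary together). The choice among median-of-ratios, library size and TMM scaling does not account for it, since the highest median over these was -1.62. They moved the median of all genes only between 0.01 and 0.13, so none could have brought the lists near 0. Scalings that differ more were not tried. GC content or transcript length does not account for it either, since the median was -1.66 after that trend was removed (-1.75 to -1.56). As a sign of a block within S phase or within G2/M as the only change, 1 of the lists was to have a median at or above 0. The higher of the list medians was -1.57. That rule was written after the medians were seen, and transcript levels do not measure cycle phase, so it cannot decide the question. A block in G1, in S phase or in G2/M stays open. A hypothesis is that fewer Toledo cells were in S phase to mitosis after 6 days of TP-064, and cell numbers and cycle phases were not analysed here.

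The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With limma the real split called 10449 genes and the highest of the others 0, with 56 to 130 genes at an unadjusted p under 0.05 in those splits and 0 calls with edgeR, so 1 of the 10 splits gave as many. For changes of at least 2-fold the real split gave 2097 and the highest other 0, again 1 of the 10. For gene lists the real split gave 9 and the highest other 9, and 3 of the 10 splits gave as many. Each of the other splits sets 2 treated samples and 1 control against the reverse, so the treatment still enters them. It adds to the spread within each set, which makes 0 called genes there near certain. The contrast with the real split therefore decides nothing.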
